A study of Mus musculus with 6 samples.

How the data were processed

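Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in lung endothelial cells isolated from mice. Per the labels, 3 libraries came from Cre-negative mice (WT) and 3 from Cre-positive mice lacking cystathionine gamma-lyase (CSE-KO), the enzyme encoded by Cth. The group and the replicate number of each library were taken from its title. Every CSE-KO library is Cre-positive and every WT library Cre-negative. Effects of Cre itself and of the loss of the enzyme therefore cannot be told apart.

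Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.3a, Picard 3.1.1 and DESeq2 1.26.0 were used on the genome build mm10. The role of each tool, the peak caller and any shift of the read ends for Tn5 are not given in the sources used here. The deposited table holds 58172 regions with a median width of 440 bp, their mm10 coordinates, the gene the authors assigned to 21839 of them, and 6 columns of values. The deposited values were treated as a score: they are whole numbers, yet the 6 libraries share median-ratio factors of 1.01 and sum to between 5242490 and 5547417, and the values up to 100 in the CSE-KO columns skip 39, 35 and 39 whole numbers. These are marks of read counts that were divided by a size factor and then rounded. Of the values up to 100, 98.53% to 100% per column equal a whole number of estimated reads after rounding. In the WT columns 99% to 100% of all whole numbers up to 100 do so, so this does not recover their reads. Higher values were not checked. A model for raw counts, planned for the case of raw counts, was not run.

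The spacing of the low values gave an estimate of what 1 read was worth in each column. It was 0.792, 0.57 and 0.498 in WT replicates 1 to 3 and 1.63, 1.53 and 1.64 in CSE-KO replicates 1 to 3. The estimated reads in regions were therefore about 6770000, 9240000 and 10520000 in WT and 3330000, 3620000 and 3370000 in CSE-KO. For WT replicate 3 a step of 1, and with it 5242490 reads, could not be separated from the estimate. The CSE-KO libraries thus rest on fewer reads, and their residual SD on the log2 scale was 0.481 against 0.306 in WT. No pair of libraries within a group was identical, so none was treated as a copy of another. Their differences were 1.95 to 2.5 times counting noise at mean values of 10 to 30 and 3.02 to 4.73 times at 300 to 1000. If reads were counted in pairs, as the simulations below assume, counting alone gives a ratio near 2. The ratio at low values therefore cannot tell separate libraries from 1 library sequenced again. These values do not show that the libraries are independent, and the labels do not say that the samples came from separate animals. The p-values measure only the spread between these samples.

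The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with eBayes and with trend and robust off, for the 58129 regions with a mean of at least 5 over the 6 libraries. Effects are CSE-KO minus WT, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of weak regions. Promoter regions are those whose centre lies within 1 kb of a transcription start site by the authors' distance, and all others are called distal. Shares of values were compared with two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3.

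A region belonged to the gene the deposited table assigns. Where the table assigns none, it went to the nearest start site within 100 kb among 12616 protein-coding genes of that table. This assigned 24624 further regions and left 11709 without a gene. Of the 21839 regions with a gene in the table, only 15754 carry a gene symbol. The rest were not given a nearest gene and could enter no gene list and no naming rule. An assignment by distance does not show that a region acts on the gene. Gene lists were fixed before the data were examined: 22 lists with 527 entries, of which 430 were matched by symbol to at least 1 region. Each list was tested with limma's camera at a preset correlation of 0.01 over all tested regions of its genes, adjusted over the lists. Estimated correlation and fry were alternatives. Named genes followed a rule fixed at the same time: every Cth region, the 12 largest changes in each direction among called regions with non-overlapping groups and at least median abundance (1 region per gene, without predicted or clone names), up to 4 genes of each called list and up to 2 of every other list, by smallest p. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

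The scripts were tested on simulated data made from the real mean values at each library's estimated depth. Reads were drawn in pairs, with a relative variance of 0.004 in the true level of each region. With 1 in 5 regions changed, the test of CSE-KO against WT on 58066 regions recovered 20.9% of 1.5-fold, 62.2% of 2-fold, 88.1% of 3-fold and 93.4% of 4-fold changes, and 4.39% of its calls were false. Of 2-fold changes it recovered 30.9% among the lowest, 62.1% among the middle and 93.3% among the highest mean values, in 3 groups of equal size. With only 200 regions changed, on 58051 regions, it recovered 0% of 2-fold and 42% of 4-fold changes, while median fitted folds stayed at 1.51, 2.03, 3.06 and 4.01 for true folds of 1.5, 2, 3 and 4. With the endothelial identity list alone lowered 1.5-fold, camera called 2 lists, that list and the VEGF list, which shares Kdr and Flt1 with it. In 10 simulations without any change, 0 regions were called and 5.11% to 5.38% had an unadjusted p under 0.05.

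Alternatives covered the pseudocount, the filter on low values, quantile and total scaling, limma's trend and robust options, a minimum fold, the replicate block, each library left out, other distances and windows, and other ways to assign regions to lists. No list of repeat-rich regions was used to remove regions. Motifs were not analysed here because no genome sequence was used. RefSeq gene positions were taken from a table of assembly GRCm38.p6, which is the same build as mm10. Python 3.11.15 scripts read the table and drew the figures.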

Results

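Lung endothelial cells of WT and CSE-KO mice, with 3 ATAC-seq libraries each, were compared to ask where the loss of cystathionine gamma-lyase, an enzyme that makes cysteine from cystathionine, is accompanied by a change in open chromatin. The deposited values summed to 5368491, 5264443 and 5242490 in the WT libraries and to 5437296, 5547417 and 5536256 in the CSE-KO libraries. The CSE-KO libraries held fewer reads, with an estimated 3330000 to 3620000 in regions against 6770000 to 10520000 in WT, where the 10520000 of replicate 3 is uncertain and may be 5242490. The first principal component carried 54% of the variance and separated the groups. The groups differ in Cre as well as in Cth, and the comparison cannot separate Cre from the loss of the enzyme.

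Cth, the targeted gene, had lower values at its promoter in CSE-KO. The values cannot tell closed chromatin from absence of this sequence in the engineered allele. The sample titles do not say which part of the gene was removed. The region on chromosome 3 from 157924836 to 157925422, centred 52 bp from the start site, had values of 195, 157 and 167 in WT and of 11, 6 and 2 in CSE-KO, or 173 ± 19.7 against 6.33 ± 4.51 (SD, n = 3 each). The change was -4.78 ± 0.46 (log2, SE), 27.4-fold lower in CSE-KO, with an adjusted p of 0.00307 by limma. No library went against its label at this gene. A region 48.2 kb away (157876830 to 157877016), assigned to Cth by distance, had 12.3 ± 2.89 in WT and 12.7 ± 3.51 in CSE-KO (adjusted p = 0.955).

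**Figure D1:**
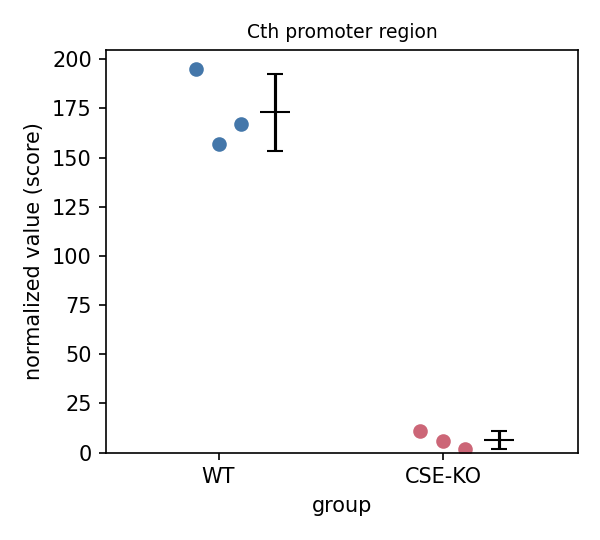
Normalized values (score, vertical axis) of the Cth promoter region in the 3 WT and 3 CSE-KO libraries. Points are libraries and the bar beside them is the mean with its SD. WT lies between 157 and 195 and CSE-KO between 2 and 11.

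Accessibility differed between the genotypes at many sites, in both directions. Of 58129 tested regions, 10057 (17.3%) changed, 4478 higher and 5579 lower in CSE-KO. Among these, 2513 were at least 2-fold higher and 3445 at least 2-fold lower. Of the weakest 10% of the regions, which shifted down in simulations without change, 188 were higher and 441 lower. The groups did not overlap at 39.5% of regions, where chance gives 10%. The 6 regions with a value over 10000, chosen after their values were seen, held 0.81% ± 0.15 of the values in WT and 5.51% ± 0.12 in CSE-KO (SD, n = 3 each), and without them 10049 regions changed.

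The rise that led the named genes was at Hspa1b, an inducible heat-shock chaperone. Its region on chromosome 17 from 34955547 to 34956764, which spans the gene's 3' end, had 11.3 ± 6.11 in WT and 786 ± 37.7 in CSE-KO (n = 3 each, log2 change 6.12 ± 0.34 (SE), adjusted p = 0.000866). The next were regions near Sfi1 (13.1-fold, 61.3 kb from the start site), Polr3k (11.8-fold, 53.4 kb), Brox (11.6-fold, 2.09 kb) and Ly6g (10.4-fold, 68.9 kb). Rises of 8.65-fold, 6.84-fold and 5.63-fold followed near Cldn34d, Kctd16 and Nucb2. The 6 regions over 10000 rose 5.06-fold to 10.9-fold. Repeat-rich regions were not removed, and whether repeated sequence adds to the rises near the named genes was not tested. The region 2.57 kb from Ftl1, the ferritin light chain with pseudogene copies that can share its reads, rose 5.44-fold, from 71.3 ± 24.1 to 381 ± 54.5. The promoter of Stx1a, a syntaxin of vesicle fusion, rose 5.04-fold. Regions near Cp, the copper carrier ceruloplasmin, and Slc4a4, a bicarbonate cotransporter, rose 4.66-fold and 4.64-fold.

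The largest falls that the naming rule took after Cth lay outside promoters. Regions near Mctp1, Mtbp and Cep68 fell by 8.04-fold, 7.61-fold and 7.33-fold. The region 36.3 kb from Bdkrb2, the bradykinin B2 receptor, fell from 305 ± 11.9 to 46.7 ± 14.6, and that 5.17 kb from Stc1, the hormone stanniocalcin 1, fell from 147 ± 17.7 to 22 ± 6.56 (n = 3 each). Regions near Ranbp2 and Elk3, an ETS-family transcription factor, fell 6.45-fold and 6.26-fold. Regions near Samd4a, Lrrfip1, Ssuh2 and Shc3 fell between 5.51-fold and 6.2-fold. The call near Shc3 ended without WT replicate 1, 2 or 3 or CSE-KO replicate 3 (adjusted p = 0.081, 0.0806, 0.0701 and 0.0555). The adjusted p of these regions, rises and falls together, ranged from 0.000804 to 0.0236. Without WT replicate 1, 2 or 3, the count of changed regions was 3602, 3684 or 3519. It was 15448 with limma's trend and robust options.

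Regions at 2 further heat-shock genes, chosen after their values were seen, rose in the same part of the gene. The first, from 34968766 to 34970047, lies at the 3' end of Hspa1a, the near-identical neighbour of Hspa1b. It had 5.67 ± 5.69 in WT and 672 ± 49.4 in CSE-KO. This 133-fold rise (adjusted p = 0.00236) was larger than the 69.3-fold rise at Hspa1b, but the naming rule did not take this region. Just downstream of Hspb1, a small heat-shock protein on chromosome 5, the region from 135890011 to 135890621 had 8.33 ± 2.08 and 212 ± 27.2 (adjusted p = 0.000833). Reads that fit both Hspa1 copies could be split between them, so the values of either copy are uncertain. The promoters rose far less, 1.68-fold at Hspa1a and 1.62-fold at Hspb1, and that of Hspa1b was not called (1.45-fold, adjusted p = 0.077).

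**Figure D2:**
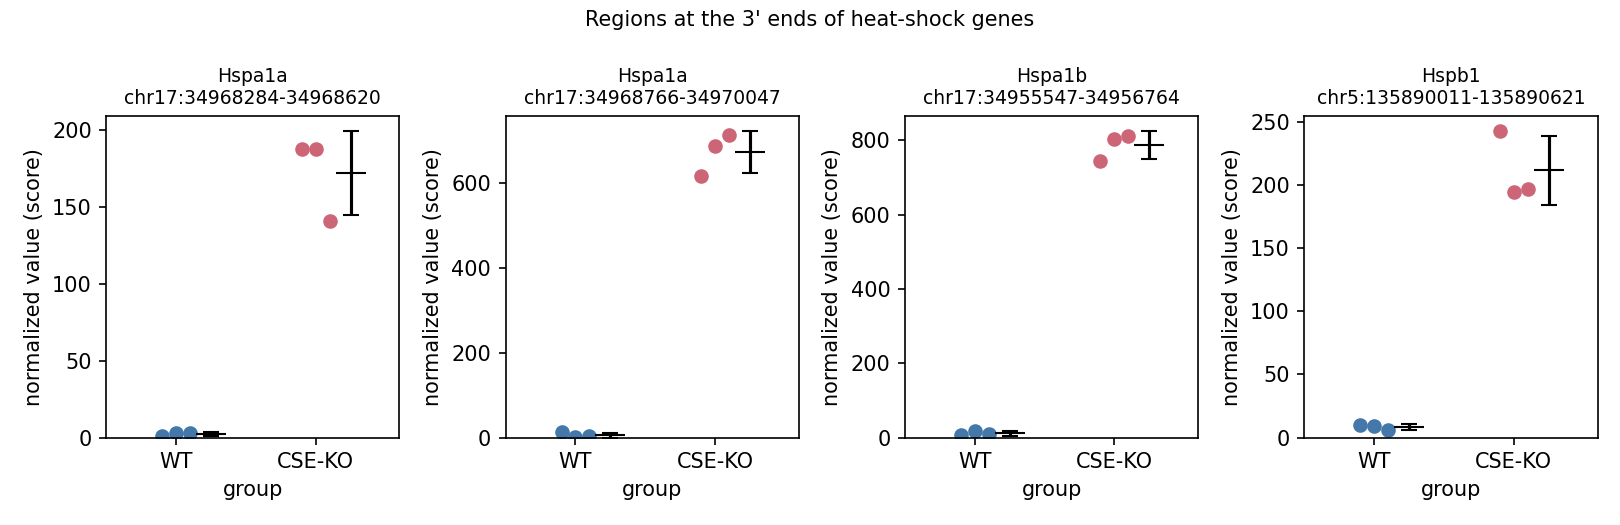
Normalized values (score, vertical axes) of 4 regions at the 3' ends of Hspa1a, Hspa1b and Hspb1 in the 3 WT and 3 CSE-KO libraries (points), with mean and SD beside them. In each region the CSE-KO libraries lie above the WT libraries, for example 743 to 812 against 6 to 18 at Hspa1b.

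Promoters and distal sites moved apart. Promoter regions had a median log2 change of 0.11 and distal regions of -0.06. Of 13246 promoter regions, 693 were higher and 436 lower, and of 44883 distal regions, 3785 were higher and 5143 lower. Promoter regions held 42.5% ± 0.75 of all values in WT and 45% ± 0.92 in CSE-KO (SD, n = 3 each), with every CSE-KO library above every WT library. With promoters taken within 2.5 kb of a start site the shares were 48.6% and 53.8%, a difference of 5.22 in place of 2.54 percentage points. The wider distance also takes in regions over 10000 that lie 1217, 1662, 1717 and 2194 bp from a start site and rose in CSE-KO. In that order their mean values were 5483, 14100, 4520 and 1609 in WT and 54680, 71360, 47750 and 13240 in CSE-KO. As a share of all values, this rise is large enough to account for the whole widening of the gap. Without the 6 regions over 10000 the difference within 1 kb was 2.91 percentage points. The two-sided exact permutation p was 0.1, the smallest this design allows, for the share and for the difference of mean log2 values.

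Gene lists were used to see where these changes fell. Regions of endothelial identity genes were lower on balance: of 191, 35 were lower and 12 higher, with a median log2 change of -0.24. The 167 distal regions among them had 33 lower and 8 higher, and tested alone, a test chosen after the data were seen, were called lower by camera (adjusted p = 0.0334, but adjusted p = 0.459 with an estimated correlation). Of 27 genes with a region, 15 had only lower calls, 4 only higher calls, 4 both and 4 none. Regions near Egfl7, Mmrn2, Flt1 (the VEGF receptor 1) and Ets1 fell 2.77-fold, 3.4-fold, 2.75-fold and 2.79-fold. The 8.11 kb distant region of Egfl7, an extracellular protein of endothelium, went from 214 ± 16.8 to 76.7 ± 6.51. Of its 24 promoter regions, 4 were called higher and 2 lower. Among these, which were chosen after their values were seen, Kdr (VEGF receptor 2) rose from a mean of 157 to 258, Tek from 163 to 267, Fli1 from 42 to 90 and Ramp2 from 60.3 to 115, while Tie1, a receptor related to Tek, fell from 163 to 67.7 and that of Egfl7 from 144 to 80. The promoter median of the list was 0.26 and the distal median -0.30.

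The list of TGF-beta signalling and endothelial-to-mesenchymal transition had 46 regions lower and 7 higher of 187, with a promoter median of 0.09 and a distal median of -0.42. Of its 28 genes, 15 had only lower calls, 5 had both and 8 had none. Regions near Smad6 and Smad7, which are inhibitors of SMAD signalling, fell 3.62-fold and 3.5-fold. Regions near Id1 and Id2, BMP-responsive inhibitors of basic helix-loop-helix factors, fell 3.09-fold and 2.52-fold, with Id1 at 588 ± 33.1 in WT and 190 ± 22.3 in CSE-KO.

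These 2 of 22 lists were called by limma's camera, with an adjusted p of 0.0374 for endothelial identity and 0.0112 for TGF-beta. With an estimated correlation neither call held (adjusted p = 0.323 and adjusted p = 0.18). The endothelial call also ended without WT replicate 2, CSE-KO replicate 2 or CSE-KO replicate 3 (adjusted p = 0.0681, 0.0983 and 0.11), and with 1 region per gene, the one nearest the start site, both lists pointed up without a call (adjusted p = 0.403 and 0.608). With the deposited annotation alone the adjusted p was 0.973 (endothelial, up) and 0.433, and with RefSeq gene spans it was 0.183 and 0.0575. Adjusted over the list alone, the endothelial list had 54 lower and 14 higher regions and the TGF-beta list 55 lower and 10 higher.

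**Figure D3:**
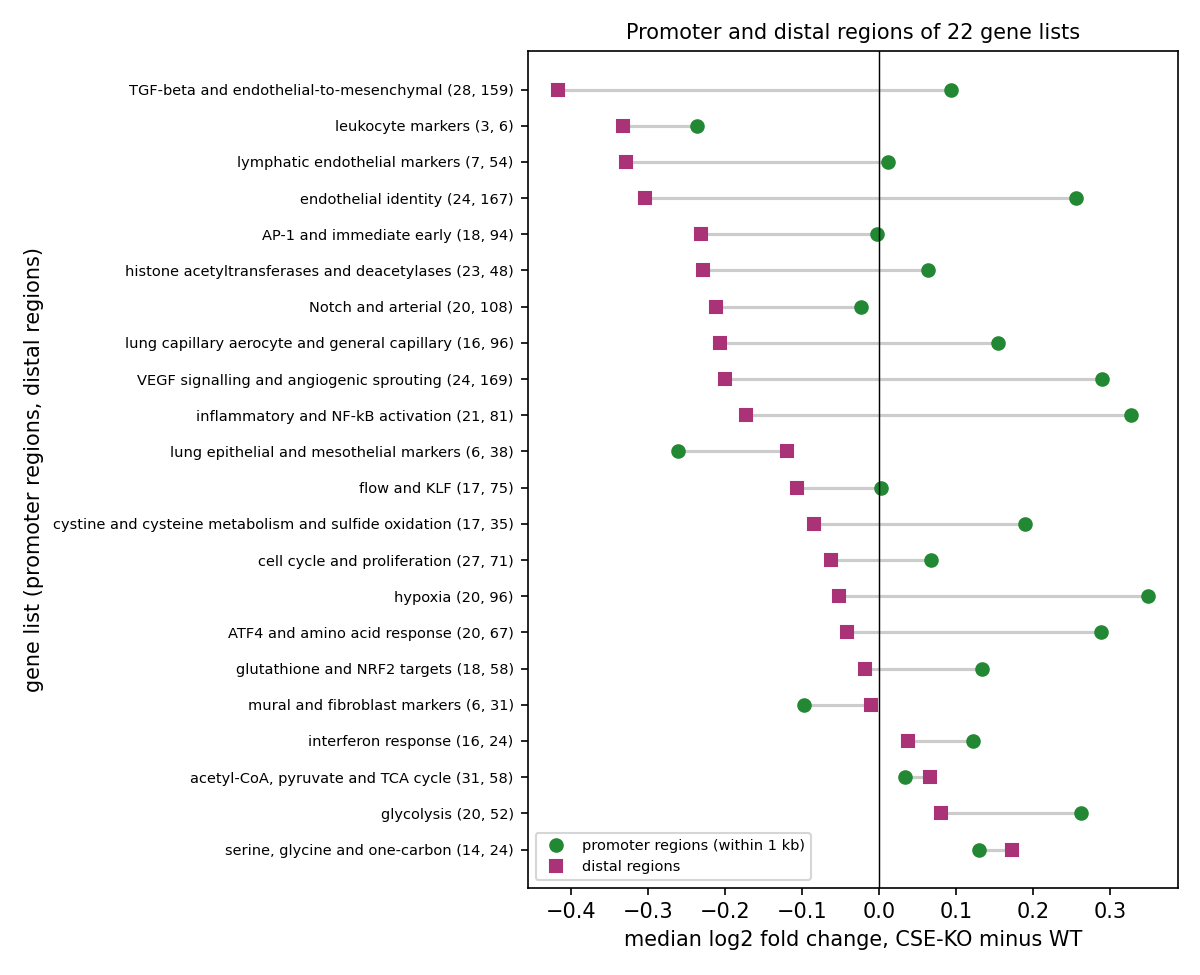
Median log2 fold change (CSE-KO minus WT, horizontal axis) of promoter regions (circles) and distal regions (squares) of 22 gene lists, with the number of promoter and distal regions in brackets. The distal median of the TGF-beta list is -0.42 and that of endothelial identity -0.30, while the promoter median of the hypoxia list is 0.35.

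None of the other 20 lists was called, and their counts follow as descriptions. Vascular lists had more lower than higher regions, except flow and KLF genes. VEGF signalling had 33 lower and 18 higher of 193 (36 and 20 adjusted over the list alone), with Angpt2 (angiopoietin 2) and Adm (adrenomedullin) falling 3.03-fold and 2.51-fold at distal regions, while the Adm promoter, looked up afterwards, rose 1.91-fold. Notch and arterial genes had 20 lower and 8 higher of 128 (22 and 10 adjusted over the list alone), with falls near Notch1 and Notch4 of 2.83-fold each. Lung capillary genes had 16 lower and 5 higher of 112 (17 and 5 adjusted over the list alone). A region 99.7 kb from Tmem100 fell 2.53-fold, and a region 65.7 kb from Hpgd, which inactivates prostaglandins, rose 2.06-fold. Lymphatic markers had 14 lower and 4 higher of 61 (15 and 6 adjusted over the list alone). Regions 11.2 kb from Prox1 and 9.38 kb from Flt4 fell 3.12-fold and 2.6-fold. Flow and KLF genes had 9 lower and 10 higher of 92 (13 and 11 adjusted over the list alone). Regions 46.1 kb from Timp3 and 52.3 kb from Mef2a fell 3.31-fold and 2.68-fold.

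Around cysteine and redox metabolism the picture was mixed. The list of cystine and cysteine metabolism had 3 regions higher and 6 lower of 52, including the Cth promoter. A region 45.8 kb from Slc7a11, the cystine importer, rose from 12.7 ± 1.53 to 40 ± 10.4 (n = 3 each, 2.95-fold). Glutathione and NRF2 targets had 6 higher and 8 lower of 76, with Ftl1 and Slc7a11 above as their leading genes. The ATF4 and amino acid list had 8 higher and 9 lower of 87. Its promoter regions had 3 higher and 0 lower (median 0.29), its distal regions 5 higher and 9 lower (median -0.04). With the deposited annotation alone, a setting chosen after the data were seen, camera called this list up (adjusted p = 0.00761). Over all its regions camera did not (adjusted p = 0.624). The promoter of Chac1, a glutathione-degrading enzyme, rose 2.21-fold from 111 ± 2 to 247 ± 0.58, and a region 20.9 kb from Ddit4, an inhibitor of mTORC1, fell 6.91-fold, while the Ddit4 promoter, looked up afterwards, rose 1.77-fold. Counts for these 3 lists were the same when adjusted over the list alone.

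Among histone acetyltransferases and deacetylases, 5 regions were higher and 7 lower of 71, as they were adjusted over the list alone. Regions near Kat2b, an acetyltransferase, and Hdac7, a deacetylase, fell 2.51-fold and 2.82-fold. Acetyl-CoA, pyruvate and TCA cycle genes had 5 higher and 5 lower of 89 (1 and 1 adjusted over the list alone), with a fall near Fh (fumarase, 2.65-fold) and a rise near Pdk3, a pyruvate dehydrogenase kinase (2.44-fold). Glycolysis had 3 higher and 0 lower of 72 (1 and 0 adjusted over the list alone), with rises at Pkm (pyruvate kinase, 2.91-fold) and Slc2a1 (the glucose transporter GLUT1, 1.71-fold). The Slc2a1 call ended without WT replicate 1, 2 or 3 (adjusted p = 0.0821, 0.0896 and 0.0568). Serine, glycine and one-carbon genes had 4 higher and 5 lower of 38, as they were adjusted over the list alone, with falls near Mthfd2l (2.35-fold) and Slc6a9, a glycine transporter (2.23-fold).

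AP-1 and immediate early genes had 14 regions lower and 7 higher of 112 (17 and 8 adjusted over the list alone). Regions near Maff and Jun fell 4.09-fold and 3.16-fold. Hypoxia genes had 15 lower and 11 higher of 116 (16 and 12 adjusted over the list alone), with a 6.26-fold rise near Ndrg1 and, near Ddit4, the distal fall beside the promoter rise. The hypoxia promoters alone, tested after promoters and distal sites were seen to differ, were called higher by camera (adjusted p = 0.0377, median 0.35), but not with an estimated correlation (adjusted p = 0.791). Inflammatory and NF-kB genes had 9 lower and 10 higher of 102 (14 and 14 adjusted over the list alone). A region near Nfkbia, the NF-kB inhibitor, fell 2.41-fold and a region near Tlr4 rose 3.32-fold. Interferon genes had 3 lower and 3 higher of 40, as they were adjusted over the list alone, with the Irgm1 promoter rising 1.78-fold. Cell cycle genes had 5 lower and 7 higher of 98 (4 and 2 adjusted over the list alone), with falls near Cdkn2b (2.25-fold) and Ccnd1 (2.01-fold). The Irgm1 call ended without WT replicate 1, 2 or 3 (adjusted p = 0.0763, 0.0546 and 0.0678) and the Ccnd1 call without WT replicate 3 (adjusted p = 0.0512). The median and the test pointed opposite ways for the inflammatory list (median 0.02, camera down) and the cell cycle list (median -0.03, camera up), and fry and camera did so for the serine and cell cycle lists.

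Markers of other cell types were counted beside these groups. Many of them had no assigned region: 11 of 20 mural, 12 of 22 lung epithelial and 6 of 24 leukocyte markers had one. Mural and fibroblast markers had 4 regions lower and 1 higher of 37, with falls near Postn (2.99-fold) and Col1a1 (2.64-fold), whose promoter, looked up afterwards, rose 2.12-fold. Lung epithelial and mesothelial markers had 2 lower and 4 higher of 44, with a 3.93-fold fall near Hopx and a 1.77-fold rise near Krt8. Leukocyte markers had 1 lower and 0 higher of 9, the promoter of Spi1, a myeloid transcription factor (169 ± 21.5 against 99 ± 7.55). The Krt8 and Spi1 calls ended without WT replicate 1, 2 or 3 or CSE-KO replicate 1, Krt8 also without CSE-KO replicate 2, and the Col1a1 fall without WT replicate 3, with adjusted p from 0.0538 to 0.0989. A region near Cd4 had 31.7 ± 6.11 in WT and 16.3 ± 6.11 in CSE-KO (adjusted p = 0.0617). For all 3 of these lists the counts were the same adjusted over the list alone.

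The share of changed regions around the engineered locus passed the test within 5 Mb but not within 10 Mb, the window of the main test. Within 10 Mb of Cth 42 of 207 regions (20.3%) changed, against 17.3% elsewhere (odds ratio 1.22, 95% interval 0.846 to 1.72, two-sided Fisher's exact test p = 0.269). Within 5 Mb the share was 25.6% of 86 regions (odds ratio 1.64, 95% interval 0.964 to 2.71, Fisher's exact test p = 0.0463). That interval includes an odds ratio of 1 although p was under 0.05. The X chromosome held 1.29% ± 0.013 of the values in WT and 1.22% ± 0.0094 in CSE-KO (n = 3 each). Regions on the Y chromosome had values in each library, 0.0039% to 0.005% in WT and 0.0061% to 0.0083% in CSE-KO, and no mitochondrial regions were in the table used here.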

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

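The tests of the added settings (group-level weights, the table's own annotation, RefSeq spans, promoter or distal regions alone with either correlation, and leaving out the 6 regions over 10000) were chosen after the data were seen. At the Cth locus the promoter fell in every setting run (log2 change -5.24 to -4.05). The count of changed regions stayed within 1.5 times of 10057 under both pseudocounts, both filters, quantile and total scaling, a 1.5-fold minimum, group-level weights and without the 6 regions. Total scaling gave 62.2% lower calls against 55.5%. With trend and robust on it was 15448 (7185 higher, 8263 lower). Leaving out a library gave 3519 to 8922 changed, 1613 to 3583 higher and 1856 to 5339 lower regions. The low values each came without 1 WT library, and the cause was not tested. With the replicate block 6013 regions changed (2594 higher, 3419 lower). The numbers did not pair the libraries, since deviations of same-numbered libraries correlated at -0.0059, -0.0105 and 0.0105, and the blocked lists kept both calls.

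The number of called lists was 2. It was 0 with an estimated correlation (adjusted p = 0.323 for the endothelial and 0.18 for the TGF-beta list), 9 by fry (which tests a list against no change, not against other regions), 1 with 1 region per gene (both lists up, 0.403 and 0.608; the hypoxia list was called up), and 1 among promoters alone (0.855, endothelial up, and 0.961). With the table's own annotation the values were 0.973 (endothelial, up) and 0.433, and the ATF4 and hypoxia lists were called up instead. With RefSeq spans 0 lists were called (0.183 and 0.0575). Leaving out a library gave 1 to 2 lists, with 0.0138 to 0.11 for endothelial identity. Among distal regions alone both lists were called, but 0 with an estimated correlation (0.459 and 0.297), as among promoters alone (0.949, endothelial up, and 0.956). The cause of these differences was not tested. For changed regions around Cth the odds ratio was 1.22 within 10 Mb (Fisher's exact test p = 0.269), 1.64 within 5 Mb (p = 0.0463), 1.17 within 20 Mb (p = 0.208) and 1.53 within 10 Mb with the replicate block (p = 0.0384), and the cause was not tested. Of 67 called regions of named genes, 7 (Shc3, Slc2a1, Irgm1, Spi1, Krt8, Ccnd1 and Col1a1) lost the call, with a library left out or the replicate block, and 0 turned direction. The promoter share and the promoter to distal difference kept their sign in all settings run (0.22 when matched on mean value, and 5.22 in place of 2.54 percentage points of share with promoters within 2.5 kb), but 3 libraries against 3 cannot pass the threshold.

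In 1 of the 10 splits of the 6 libraries, the real one, 10057 regions changed, and the highest of the other splits was 0. For the lists it was also 1 of 10, with 2 lists called and 0 as the highest other. These are too few splits for a share under 0.05. Every other split also puts libraries of both genotypes in each group, which adds the genotype difference to the spread. The 0 of the other splits is therefore not the level that chance alone would give. Count models, loess offsets and motif tests were not run because the values are a rounded score and no genome sequence was used. The table has no comparison by the authors. Recovery differed with the mean value: in data simulated at the estimated depths 30.9% of 2-fold changes were recovered among the lowest mean values and 93.3% among the highest.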

Other observations

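Genes with many changed regions were looked at after the data were seen. Elmo1, which regulates the Rac GTPase, had 11 of 20 regions lower and 0 higher. Asap1 had 9 of 15, Smad7 8 of 19, Rin3 6 of 13 and Smad6 6 of 12 lower, with 0 higher at each. Col4a2, a collagen of the basement membrane, had 5 of 11 lower. In the other direction Hibadh had 6 of 7 regions higher, Chst11 5 of 11, Sp140 5 of 6 and Sfi1 8 of 8. The median log2 change over their regions was 1.29, 0.53, 3.85 and 3.48, in that order. The 6 regions over 10000 rose by 2.34 to 3.45 on that scale. Whether repeated sequence with shared reads adds to the counts at Sp140 and Sfi1 was not tested. Promoters that rose included Mt2, a metallothionein (from a mean of 63.7 to 215), and a promoter region of Nes, nestin (from 29 to 88.3), and promoters that fell included Pdgfd (from 301 to 108) and Smad9 (from 244 to 100).

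Of the tests below, those of the repeat-like regions, of Hspb1, of heat-shock gene bodies and of the 3 other-cell lists were chosen only after the result was seen.

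The 6 regions with a value over 10000 in any library lie at the predicted genes Gm10800, Gm10801, Gm10719 and Gm21738, beside the ribosomal RNA gene Rn18s-rs5 and at 35305218 on chromosome 9. They took 0.81% ± 0.15 of the values in WT and 5.51% ± 0.12 in CSE-KO, and each rose, by 5.06-fold to 10.9-fold. Counting noise at the lower depth of the CSE-KO libraries is argued against as the cause. The smallest log2 change was 2.34 and the highest in 10 simulations without change was 0.17. Other effects of depth were not simulated and stay open. Within WT the share was 0.96%, 0.81% and 0.66% in replicates 1 to 3. It fell as the estimated reads rose (6770000, 9240000 and 10520000, the last uncertain). Background DNA spread evenly over the genome may still contribute: the weakest 10% of the regions had a median of -0.24, no higher than the simulated -0.22 to -0.20, and differed by -3.74 per kb (CSE-KO minus WT), within the -3.77 to -3.03 of simulations without change. These values show no even addition, yet one of up to 0.72 per kb would go unseen, and the number of genomic copies behind each region was not measured. A biological rise of repeat accessibility with the genotype stays open and was not tested.

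The rises at the 3' ends of Hspa1a, Hspa1b and Hspb1 do not come from reads shared by the Hspa1 copies alone, since Hspb1 rose by 4.53 on the log2 scale. A candidate explanation is transcription of heat-shock genes, during handling or in the animals. The median log2 change of 64 regions of 20 other heat-shock genes was 0.05, at the 53.8 percentile of 10000 matched random lists, with 6 higher and 6 lower. In their gene bodies and at their 3' ends, 4 of the 20, among them Hsph1, Hsp90ab1 and Hspa8, had a higher region, against a median of 1 in random lists, of which 94.7% had fewer than 4, short of the share set for this test. Whether handling, Cre or the loss of the enzyme set this cannot be told apart. All CSE-KO libraries share the rises and Cre, and no label gives the handling.

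The gap between promoter and distal changes was 0.167, above 0.0196, the highest of 10 simulations at the estimated depths. This argues against counting noise at the lower depth as the only cause. Other effects of depth were not simulated. More leukocyte, mural and lung epithelial cells in CSE-KO stay open: the 90 regions of those lists were lower when pooled (median -0.14, unadjusted p = 0.0203 by limma's fry, exact permutation p = 0.1, the smallest this design allows), and each list pointed down by fry (adjusted p = 0.0399 for leukocyte, 0.085 for mural and 0.134 for lung epithelial markers), with medians of -0.26, -0.01 and -0.12. None pointed up by fry in the main fit. Only 6 of 24 leukocyte, 11 of 20 mural and 12 of 22 lung epithelial markers had an assigned region. These lists could therefore fail to rise even with more such cells. The pooled test met its rule, which was written after the result was seen. Split by list, only the leukocyte list passed, and the lung epithelial list had 4 higher and 2 lower regions. By camera the mural and lung epithelial lists pointed up with 1 region per gene, the table's own annotation or RefSeq spans, all without a call. The leukocyte list pointed down in those settings, also without a call. A lower share of endothelial cells may also remain, since endothelial promoters had a median of 0.26 but 66.7% of them were above 0, short of the 75% set beforehand. A change of chromatin with the genotype is a hypothesis that these libraries leave open.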
